A study of Rattus norvegicus with 6 samples.

How the data were processed

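Kidney RNA of Dahl salt-sensitive (S) rats was compared with that of congenic rats, which carry a chromosome 9 segment of the R strain on the S background. Per the series' design text, 6 male rats of each strain were born on one day, weaned at 30 days, caged with 1 S and 1 congenic rat per cage, fed a diet with 2% salt and killed at 53 days. RNA of 2 rats was pooled into 1 sample, and 3 such pools per strain were each hybridised to 1 Affymetrix Rat 230 2.0 array. The 6 arrays were assigned to the S and congenic groups from the sample labels. The pools come from different rats, so the spread between arrays holds both biological and technical variation, with the variation between rats reduced by pooling.

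The deposited values were intensities, 1 MAS5 signal per probe set on a linear scale, per the submitters' processing notes and from the values themselves. MAS5 combines the perfect match and mismatch probes of a probe set after background correction and scales every array to one target. The version, the target and the detection calls were not given in the sources used here. The mean without the highest and lowest 2% of probe sets was 150 on every array, so the arrays had already been brought to one scale. Because of this scaling, a shift common to most transcripts could not be seen. Median signals ran from 42.9 to 46.0. Scanner files were not used here. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.11.

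Gene symbols came from the platform annotation, updated through the gene ID to the RefSeq table of the rat assembly GRCr8, which was used for symbols and chromosomes only. Of 31099 probe sets, 20832 had 1 gene symbol, 436 had several and 9780 control-free probe sets had none, and 20764 of those with 1 symbol were matched to GRCr8. No gene was named from a probe set with several symbols, and an unnamed probe set is unnamed here rather than known to lack a gene.

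The main comparison used log2(signal + 16), so fold changes of dim probe sets are understated. The 57 Affymetrix control probe sets were left out, as were 12417 probe sets whose mean over all 6 arrays lay below the 40th percentile, a linear signal of about 25.0. The remaining 18625 probe sets were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 2-sided p-values and Benjamini-Hochberg adjustment at 0.05. Fold changes are congenic over S. An exact permutation test of 3 against 3 arrays cannot give a p under 0.1, so none was used for single genes. On simulated data with 200 changed probe sets among 18625, the same fit recovered 51% of changes of 1.5-fold, 89.5% of 2-fold and 99% of 3-fold changes, with 4, 7 and 10 false calls. The simulated changes were set on the log2(signal + 16) scale, and probe sets varied independently. Recovery is therefore overstated for the same fold of signal in dim probe sets.

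For gene lists and the chromosome 9 set test, each gene was represented by its probe set with the highest mean, which left 10648 genes. The 21 lists covered proximal tubule transport, the thick ascending limb and distal convoluted tubule, the collecting duct and inner medulla, the renin-angiotensin and kallikrein-kinin systems, vasoactive hormones and receptors, arachidonic acid enzymes, tubular injury and fibrosis, immune cells, oxidative stress and glutathione, fatty acid oxidation, immediate early genes, the circadian clock, heat shock and the unfolded protein response, cholesterol synthesis, cell cycle, glomerulus and endothelium, and markers of blood, fat, adrenal gland, muscle and urothelium. They held 367 symbols, of which 323 had a measured probe set and 277 were tested. Lists were tested with limma's camera at a preset correlation of 0.01 and adjusted over the 21 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were alternatives. With 1 simulated list shifted by 0.2 on the log2 scale, camera called it and 0 of the 20 unshifted lists. Those simulated genes varied independently, which real genes do not. For chromosome 9, the share of tested probe sets at an unadjusted p under 0.05 was compared with that of all other chromosomes by a 2-sided Fisher's exact test over the tested probe sets with a chromosome, and the genes of the chromosome were tested with camera.

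Genes were named by a rule. Where fewer than 5 genes in a direction passed the adjusted threshold, the 10 named were those with the smallest unadjusted p under 0.01, an absolute log2 fold change of at least 0.5 and no overlap between the groups. In addition, the rule took the 2 members of each list with the smallest p (4 for lists past the camera threshold), any list member past the threshold adjusted over its list alone, and the 3 chromosome 9 genes with the smallest p. The grouping, the test, the lists, the naming rule and all alternatives but 1 were chosen before the data were examined. The alternatives were other pseudocounts (1 and 64), quantile normalization and median centring, no filter and a filter at the 60th percentile, eBayes without the trend or with robust moderation, array weights, the replicate number as a block, a plain t-test per probe set, the mean of a gene's probe sets, the other set tests, a stricter p of 0.01 for chromosome 9 and leaving out each array in turn. Setting the S arrays against congenic array 2 alone was added after liver and adrenal transcripts had been seen on the other congenic arrays. In that fit the spread comes from the S arrays, and the single congenic array is assumed to vary like them. Alternatives to the eBayes settings, the array weights and the plain test were run for probe sets only. Figures were drawn with matplotlib 3.10.9.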

Results

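Transcript levels were measured in 6 pools of rat kidney RNA, 3 from Dahl S rats and 3 from congenic rats, each pool made from 2 rats on a 2% salt diet. Dahl S rats develop hypertension on a salt-rich diet, and the congenic strain differs from them by a segment of chromosome 9 in which the study, by its title, placed a blood pressure locus. The comparison asks which kidney transcripts differ between the strains. The arrays resembled each other, with Spearman correlations across probe sets of 0.969 to 0.977. The first principal component, 29.2% of the variance, set congenic replicate 1 apart. The 3' over 5' signal ratio of actin, a sign of RNA integrity that increases as RNA degrades, was 9.42, 8.13 and 6.54 on the S arrays and 6.15, 6.64 and 7.17 on the congenic arrays. The same ratio of Gapdh was 1.77, 1.66 and 1.505 on the S arrays and 1.63, 1.62 and 1.68 on the congenic arrays.

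Genes of the heat shock and unfolded protein response were higher in congenic kidneys as a list by camera (adjusted p = 2.47e-19), a call that was lost with an estimated correlation (adjusted p = 0.497) and with fry (adjusted p = 0.218). All 15 tested members of the list had a positive log2 fold change, with a median of 0.26. Of the 15, 13 had no overlap between the groups, where chance gives 10% and all tested probe sets gave 12.5%. The members varied together across arrays, so the 13 are not independent observations. The inducible Hsp70 chaperone Hspa1a measured 628 ± 67.8 in S and 1013 ± 140 in congenic pools (signal, mean ± SD, n = 3 each), a log2 fold change of 0.67 (SE 0.10). Its co-chaperone Dnajb1 went from 678 ± 85.3 to 958 ± 89.1, a log2 fold change of 0.49 (SE 0.096), and the Hsp110 chaperone Hsph1 from 1143 ± 115 to 1522 ± 144, a log2 fold change of 0.41 (SE 0.087). Ddit3, the stress transcription factor CHOP, went from 225 ± 41.0 to 317 ± 13.8, a log2 fold change of 0.48 (SE 0.12).

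Of the cytosolic and mitochondrial chaperones, Hspb1 rose by 0.51 on the log2 scale, Hspe1 by 0.14 and Hspd1 by 0.13. Of the genes of the endoplasmic reticulum, Pdia4 rose by 0.40, Dnajb9 by 0.30, Herpud1 by 0.26, Hspa5 (BiP) by 0.22 and Hsp90b1 by 0.21, and the transcription factors Xbp1 and Atf4 by 0.26 and 0.23. With the 4 genes above, these make 14 that passed limma's test adjusted over the list alone, whereas 0 of the 15 passed it over all probe sets, where the adjusted p of Hspa1a was 0.178. Calr, at 0.14, passed neither. S replicate 1, the array with the highest actin 3' over 5' ratio, had the lowest signal of all 6 arrays for 14 of the 15 genes, and without it the log2 fold changes of Hspb1, Xbp1, Atf4 and Hsp90b1 were 0.34, 0.16, 0.15 and 0.10. Against congenic array 2 alone, added after the data were seen and with the spread taken from the S arrays, the median was 0.26 and 5 genes passed over the list alone.

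**Figure D1:**
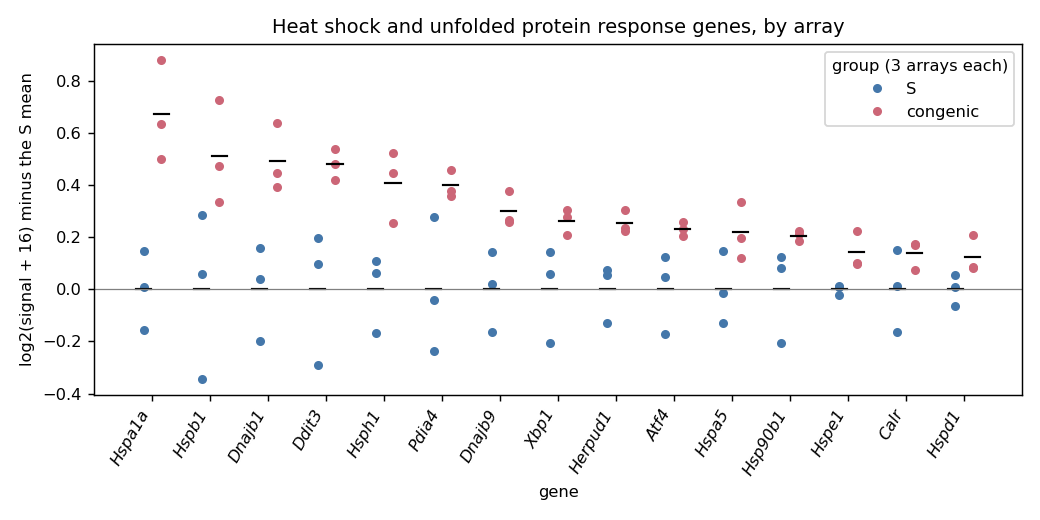
Heat shock and unfolded protein response genes on each array, as log2(signal + 16) minus the mean of the 3 S arrays. Points are arrays and black bars are group means (n = 3 pools each), and the congenic mean lies above the S mean for all 15 genes.

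Immediate early genes, which respond within minutes to growth factors and stress, were higher as a list by camera (adjusted p = 0.000436), a call lost with an estimated correlation (adjusted p = 0.497). Of 18 tested members 17 had a positive log2 fold change, with a median of 0.21. Fos measured 187 ± 58.0 in S and 281 ± 79.7 in congenic pools (n = 3 each), a log2 fold change of 0.56 (SE 0.23), and Jun 706 ± 193 and 910 ± 31.7, a log2 fold change of 0.40 (SE 0.16). Myc had a log2 fold change of 0.44 and Atf3 of 0.26. None of the 18 passed limma's test, whether adjusted over all probe sets or adjusted over the list alone (0 genes each), and 4 had an unadjusted p under 0.05. Without S replicate 1, the array with the actin ratio of 9.42, the median was 0.054 and the call ended (adjusted p = 0.129), with Fos at 0.29 and Jun at 0.16. Without congenic replicate 1, Myc was at 0.24.

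Genes of the collecting duct and inner medulla were also higher as a list by camera (adjusted p = 0.00210), again not with an estimated correlation (adjusted p = 0.497). Of the 20 tested members 14 had a positive log2 fold change, with a median of 0.14. The water channel Aqp3 measured 1000.1 ± 141 in S and 1350.0 ± 185 in congenic pools (n = 3 each), a log2 fold change of 0.43 (SE 0.11). The vasopressin-regulated channel Aqp2 measured 2722 ± 224 and 3198 ± 209, a log2 fold change of 0.23 (SE 0.070). The glucocorticoid-induced gene Tsc22d3 had a log2 fold change of 0.41, and the myo-inositol transporter Slc5a3, which is induced by hypertonicity, of 0.30. No member passed limma's test over all probe sets or adjusted over the list alone (0 of 20 each). The call ended without S replicate 1 (median 0.069, adjusted p = 0.0882, with Tsc22d3 at 0.23 and Slc5a3 at 0.15) and without congenic replicate 2 (median 0.10, adjusted p = 0.0734).

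Markers of 2 tissues next to the kidney tubule differed as lists by camera, urothelium with an adjusted p of 0.00210 and adrenal gland with 0.0267, and neither with an estimated correlation (adjusted p = 0.497 for each). All 5 tested genes of the urothelium, which lines the renal pelvis, were lower in congenic pools, with a median log2 fold change of -0.29. The uroplakins Upk1b, Upk1a and Upk3a had log2 fold changes of -0.29, -0.29 and -0.35, and the keratin Krt19 of -0.16. Upk3a was at -0.19 without congenic replicate 1 and Krt19 at -0.089 without congenic replicate 3. Of these members 0 passed adjusted over the list alone or over all probe sets. With each array left out in turn, camera at the preset correlation still called the urothelial list (median -0.32 to -0.20, adjusted p = 0.000583 to 0.0245). Against congenic array 2 alone, with the spread of the S arrays, its median was -0.10 and it was not called. The 4 tested adrenal genes, of which Cyp11a1, Hsd3b1 and Star serve the first steps of steroid synthesis, were higher, with a median log2 fold change of 1.66, from 1 array. Congenic replicate 3 had signals of 1598 for Cyp11a1, 2080 for Hsd3b1, 1085 for Star and 593 for Cyp21a1, where the other 5 arrays lay at 40.9 to 48.2, 43.9 to 71.0, 9.13 to 15.6 and 10.3 to 27.4. Of the adrenal members, too, 0 passed adjusted over the list alone or over all probe sets. The call ended without S replicate 2 (adjusted p = 0.0639) and without S replicate 3 (adjusted p = 0.0721), and without congenic replicate 3 fewer than 3 members passed the filter, with Cyp11a1 at a log2 fold change of 0.094 and Hsd3b1 at 0.064.

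Liver transcripts, chosen after their values were seen, stood out in congenic replicate 1. Albumin (Alb) measured 6683 there and 19.3 to 56.7 on the other 5 arrays, and Serpina1, the gene of alpha-1-antitrypsin, 872 against 3.51 to 14.6. Cps1, a urea cycle enzyme, measured 711 against 27.6 to 32.1, and Ttr, the gene of transthyretin, 555 against 19.1 to 30.4. That array had 40 probe sets more than 2-fold above the mean of the other 5 arrays on the log2(signal + 16) scale. Congenic replicate 3 had 18, whereas the remaining arrays had 0 to 2. In the other direction, 27 probe sets lay more than 2-fold below on S replicate 1 and 7 to 15 on each of the other 5 arrays.

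**Figure D2:**
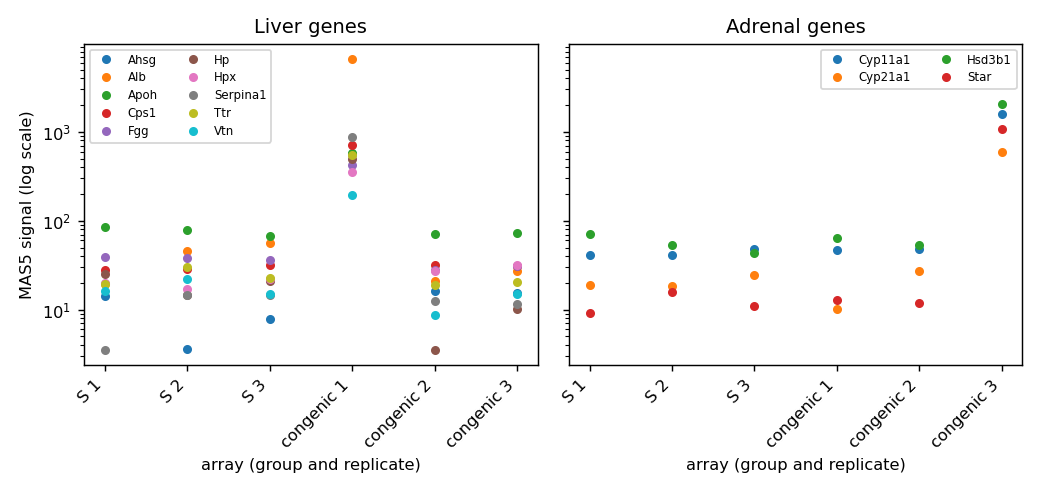
Signals of adrenal and liver genes on each of the 6 arrays, on a log axis, 1 point per gene and array. Adrenal genes such as Cyp11a1 (1598) stand apart on congenic replicate 3 and liver genes such as Alb (6683) on congenic replicate 1.

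Among single genes, the named ones with higher signals in congenic pools were led by Luzp1, at 118 ± 3.54 in S and 186 ± 8.45 in congenic pools (n = 3 each), a log2 fold change of 0.59 (SE 0.082), and by Hspa1a. Plekhj1 had a log2 fold change of 0.76, the Ras-like GTPase gene Rrad of 0.72 and Kctd11 of 0.64. Grem1, a secreted antagonist of bone morphogenetic proteins, measured 369 ± 31.2 and 584 ± 134, a log2 fold change of 0.62 (SE 0.13). The hypoxia-inducible genes Ndrg1 and Ankrd37 had log2 fold changes of 0.56 and 0.55, the exchange factor gene Arhgef10l of 0.56 and the macrophage growth factor gene Csf1 of 0.53. A second probe set of Ndrg1 had a log2 fold change of 0.15, and the other 3 of Csf1 ranged from -0.28 to 0.25.

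The named genes with lower signals were led by Rimbp2, at 466 ± 46.9 in S and 299.6 ± 23.0 in congenic pools (n = 3 each), a log2 fold change of -0.61 (SE 0.088). Its other 3 probe sets had log2 fold changes of -0.32, -0.36 and -0.46. The sialyltransferase gene St3gal2 had a log2 fold change of -0.74 (-0.39 in a second probe set), the uncharacterised LOC102548459 of -0.69, the cornified envelope gene Sprr1a of -0.67 and the carboxylesterase gene Ces1e of -0.52. Zfp619, Actmap, Fbf1, Ndp (norrin) and Sphkap had log2 fold changes of -0.55, -0.53, -0.53, -0.52 and -0.51. None of these 20 genes passed limma's adjusted threshold, and all were taken by the rule for unadjusted p.

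Over all 18625 probe sets, limma called 0 at an adjusted p under 0.05, with a smallest adjusted p of 0.145, and the plain test without moderation also called 0. At an unadjusted p under 0.05 there were 1232 probe sets, 577 higher and 655 lower in congenic pools, where 931 would be expected by chance. At 0.01 there were 259, 130 higher and 129 lower, against 186 by chance. The groups did not overlap for 2328 probe sets, or 12.5%, where chance gives 10%. Without congenic replicate 2, St3gal2 passed (log2 fold change -1.01, adjusted p = 0.0264), and without S replicate 3, 3 unnamed probe sets passed (smallest adjusted p = 0.0432).

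Of the lists on tubular transport and vasoactive systems, that of the collecting duct passed camera, as given above, and those for the other segments and systems did not. The renin-angiotensin and kallikrein-kinin list had 7 of 9 members lower and a median of -0.047 (adjusted p = 0.157), although fry, which tests for a common direction without comparing with other genes, gave an adjusted p of 0.00801. Its member Agtrap, whose product promotes internalisation of the angiotensin receptor, fell from 778 ± 60.6 to 647 ± 28.2 (n = 3 each), a log2 fold change of -0.26 (SE 0.070), and was the only member of this list to pass when adjusted over the list alone. Enpep had a log2 fold change of -0.11. Proximal tubule transport (17 genes, 12 lower) had a median of -0.043, with Lrp2 at -0.086 and Aqp1 at 0.069. That list passed downward without congenic replicate 1, the array with liver transcripts (median -0.12, adjusted p = 0.00150), whereas without S replicate 1 its median was 0.033 (adjusted p = 0.593). Against congenic array 2 alone the proximal tubule median was -0.070. The thick ascending limb and distal convoluted tubule list (14 genes, 9 higher) had a median of 0.022, with the chloride channel subunit Bsnd at -0.21 and the potassium channel Kcnj1 at 0.26. Vasoactive hormones and receptors (13 genes, 7 lower) had a median of -0.086, with Adra2a at 0.33 and Ptgs1 at -0.23, and the arachidonic acid enzymes (12 genes, 9 lower) a median of -0.067, with Cyp4a8 at 0.13 and Ephx1 at -0.14.

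The remaining lists did not pass camera at the chosen settings either. Tubular injury and fibrosis (18 genes, 14 higher) had a median of 0.069 (adjusted p = 0.0505), with Ccn2 at 0.17 and Acta2 at 0.22, and passed without S replicate 3 (0.14, adjusted p = 0.000103) and without congenic replicate 2 (0.10, adjusted p = 0.00290). Without S replicate 2 its median was 0.016 (adjusted p = 0.675). Fat markers (8 genes, 7 lower) had a median of -0.21 (adjusted p = 0.0505), with Adipoq at -0.25 and Cidec at -0.18, and passed without S replicate 1, congenic replicate 2 or congenic replicate 3 (adjusted p = 4.04e-05, 0.0333 and 0.00739). Without congenic replicate 1 its median was -0.032 (adjusted p = 0.429). Both lists passed with pseudocount 1 (adjusted p = 0.0497) and with median centring (adjusted p = 0.0410). Fatty acid oxidation (16 genes, 12 lower) had a median of -0.036, with the mitochondrial coactivator Ppargc1a at -0.23 and Ehhadh at -0.11, and passed with quantile normalization (adjusted p = 0.0494). The circadian clock (17 genes, 13 lower) had a median of -0.045, with Hlf at -0.21 and Usp2 at -0.26, and muscle markers (4 genes, 3 lower) -0.13, with Myh11 at -0.28 and Des at -0.23. Each of these 3 passed downward without S replicate 1 (adjusted p = 0.0267). Cell cycle genes (19, 12 higher) had a median of 0.042, with Mcm6 at 0.30 and Cks2 at 0.18, and passed without S replicate 3 (0.11, adjusted p = 0.0238). Immune cells (16 genes, 9 higher) had a median of 0.025, with Cxcl10 at -0.29 and Icam1 at 0.20, oxidative stress (19 genes, 12 higher) 0.041, with Cybb at -0.34 and Sod3 at 0.17, and cholesterol synthesis (13 genes, 7 higher) 0.00074, with Sqle at -0.36 and Dhcr7 at 0.18. Glomerulus and endothelium (15 genes, 8 lower) had a median of -0.049 but a mean of 0.0044 and an upward camera direction, with Ehd3 at 0.44 and Nphs1 at -0.27. Blood (5 genes, 3 higher) had a median of 0.0021 and an upward camera direction but a mean of -0.039, with Hbb at 0.090 and Ahsp at -0.32.

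**Figure D3:**
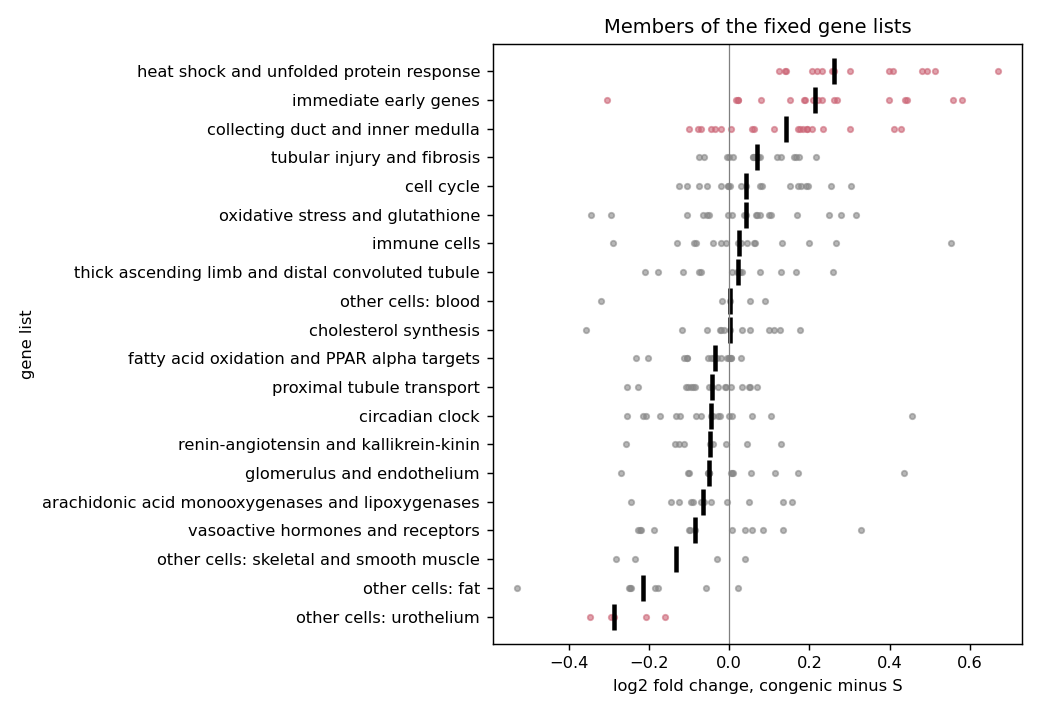
Log2 fold changes, congenic over S, of the tested members of each gene list, 1 point per gene, with a black bar at the list median and lists past camera in red. The heat shock list lies above 0 for all 15 genes and the urothelium list below 0 for all 5, and the adrenal list (median 1.66) is left out as off the scale.

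Chromosome 9, which carries the introgressed segment, did not hold a larger share of differing probe sets than the other chromosomes. Its strongest gene, the adhesion receptor Adgrf1, measured 497 ± 21.8 in S and 359 ± 12.9 in congenic pools (n = 3 each), a log2 fold change of -0.45 (SE 0.066, limma adjusted p = 0.145). The transcription factor Tfap2b, needed for development of the distal nephron, had a log2 fold change of -0.29 (SE 0.072), and its other 2 probe sets of -0.22 and -0.28. The mitochondrial carrier Slc25a23 had a log2 fold change of 0.50 in 1 probe set and -0.0034 in another. At an unadjusted p under 0.05 there were 28 of 539 probe sets (5.19%) on chromosome 9 and 901 of 13460 (6.69%) elsewhere, an odds ratio of 0.764 (95% interval 0.499 to 1.13, Fisher's exact test p = 0.186). The 411 genes of the chromosome had a median log2 fold change of -0.012, and camera did not call them. Against congenic array 2 alone, with the spread of the S arrays, the odds ratio was 1.14 (Fisher's exact test p = 0.507). Which of these genes lie within the introgressed segment was not analysed here.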

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

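Of the alternatives given here, the comparison of the S arrays with congenic array 2 alone was chosen after the data were seen, and the others before. Under the alternatives run for gene lists, the heat shock list stayed upward (median 0.19 to 0.31) and was called by all but the estimated correlation and fry. Lists were not run under the other eBayes settings, array weights or the plain test. Of 1230 values of named genes under the alternatives, 1228 kept their direction and 1 passed the adjusted threshold. The genes had been chosen by their p on the same arrays, so the kept direction is no independent support. The number of lists called was 3 with the filter at the 60th percentile, where the adrenal and urothelial lists had too few members for a value, 0 with an estimated correlation and 1 with fry. With the estimated correlation the medians stay at 0.26, 0.21, 0.14, 1.66 and -0.29 for heat shock, immediate early, collecting duct, adrenal and urothelial genes. Every adjusted p was at least 0.497, as correlated members widen the error and the adjustment gave these lists a tied value. Unadjusted, camera's p was 0.0267, 0.173, 0.163, 0.236 and 0.0625 in that order. With fry the medians are again 0.26, 0.21, 0.14, 1.66 and -0.29, and the adjusted p 0.218, 0.592, 0.584, 0.599 and 0.227. Leaving out each array in turn, the medians ran from 0.054 to 0.31 for immediate early genes, 0.069 to 0.17 for the collecting duct, and 0 to 3 probe sets passed the adjusted threshold. The adrenal median ran from 1.63 to 2.47 over the other 5 arrays left out; without congenic replicate 3 the list had no value, and Cyp11a1 and Hsd3b1 had log2 fold changes of 0.094 and 0.064. Against congenic array 2 alone, where the S arrays give the spread, 5 heat shock genes passed over the list alone, the urothelial median was -0.10, the chromosome 9 odds ratio 1.14, the log2 fold change of Nphs1 0.028 and of Hsd3b1 -0.035, and 786 probe sets passed an unadjusted p of 0.05, 367 of them higher; the cause was not tested, beyond the fewer arrays. Without a filter 1837 passed it, 868 higher, as more probe sets were tested, and without S replicate 3, 884 were higher.

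The replicate numbers showed no clear pairing of the arrays, though 3 arrays per group cannot exclude one. Same-numbered S and congenic arrays had correlations of deviations of 0.043, 0.022 and 0.017, against -0.052 to 0.036 for the others. S replicate 3 correlated best with congenic replicate 2. With the replicate block 0 probe sets passed the adjusted threshold and 1314 the unadjusted one, against 1232 without it, and 7 lists were called, with injury (adjusted p = 0.0268) and fat (adjusted p = 0.00134) gained. With the replicate block and median centring together 1 probe set passed, for which several genes are annotated (log2 fold change 1.09, adjusted p = 0.0146).

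Medians of some lists that camera did not call in the main fit changed sign under an alternative, and the cause was not tested. Cholesterol synthesis was at -0.0016 with median centring, with or without the replicate block, and -0.00067 with pseudocount 64. Blood was at -0.00025 with median centring, with or without the replicate block. Muscle was at 0.0054 without a filter, and oxidative stress was at -0.0017 and the thick ascending limb at -0.0035 with quantile normalization. Against congenic array 2 alone, injury was at -3.72e-05, immune cells at -0.067 and glomerulus at 0.051. Leaving out each array in turn gave -0.036 to 0.050 for cholesterol synthesis, -0.089 to 0.048 for glomerulus, -0.020 to 0.063 for immune cells, -0.15 to 0.13 for blood, -0.11 to 0.00071 for arachidonic acid enzymes, -0.12 to 0.033 for proximal tubule, -0.0044 to 0.038 for thick ascending limb and -0.094 to 0.0079 for vasoactive genes.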

Other observations

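The sets of further heat shock, unfolded protein, hypoxia, adrenal and liver genes, the adrenal tests and the test of the share of medulla were chosen after the results they follow up were seen, as was the estimate without single arrays used to judge tissue handling. Of 18 tested genes of a second heat shock set, 15 had a positive log2 fold change, with a median of 0.15, and 7 passed limma's test adjusted over the set alone. The small heat shock protein Cryab measured 2233 in S and 2755 in congenic pools (n = 3 each), a log2 fold change of 0.30, and the Hsp90 co-chaperones Chordc1, Fkbp4, Stip1 and Ahsa1 had log2 fold changes of 0.37, 0.34, 0.31 and 0.27. Adjusted over the 6 sets tested this way, limma's camera gave an adjusted p of 2.31e-08, but an adjusted p of 0.0548 with an estimated correlation. Cryab, Chordc1 and Ahsa1 had been seen before the set was written; without these 3, 12 of 15 were higher, 0 passed adjusted over the set alone, the median was 0.11 and the adjusted p 0.000163, and 0.0659 with an estimated correlation.

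A second unfolded protein set did not pass. Of its 20 genes 12 were higher, with a median of 0.039 (adjusted p = 0.0849, and adjusted p = 0.240 with an estimated correlation). Manf and Sdf2l1 had log2 fold changes of 0.35 and 0.25, and the amino acid response gene Asns of -0.34. In a hypoxia response set, 11 of 18 genes were higher, with a median of 0.048 (adjusted p = 0.00402, and adjusted p = 0.0864 with an estimated correlation). Ankrd37 and P4ha1, at 0.55 and 0.39, passed adjusted over the set alone, and Ero1a was at 0.24, whereas Vegfa was at 0.039 and Pgk1 at -0.033. Ankrd37 and Ndrg1 had prompted that set, and without these 2 it did not pass: 9 of 16 were higher, with a median of 0.039 (adjusted p = 0.0502, and adjusted p = 0.240 with an estimated correlation).

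There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split gave 1232 probe sets at an unadjusted p under 0.05 and the highest other split 1363, so that 2 of 10 gave as many. The latter set S replicates 1 and 2 and congenic replicate 1 against the rest. The real split called 5 lists and the highest other 10, and 7 of 10 called as many. For the heat shock list the real split gave a camera p of 1.17e-20 and the smallest other p was 1.34e-06, so that 1 of 10, the real one, gave a p as small. Every split joining S replicate 1 with 1 other S array and 1 congenic array gave a camera p of 1.34e-06 to 2.46e-05. Every split other than the real split still put most S arrays opposite most congenic arrays, so each kept part of any strain difference. A small p there thus cannot tell whether camera at this setting calls the list where no difference exists. Splits joining S replicate 1 with 2 congenic arrays gave a camera p of 0.633 to 0.995.

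For the higher heat shock genes, adjusting for RNA quality left most of the difference. With the 3' over 5' ratio as a covariate the median was 0.22 (95% interval over members 0.19 to 0.40), 82.9% of its value. The list still passed camera at the preset correlation, though without any covariate its call was lost with an estimated one (adjusted p = 0.497). This cannot exclude RNA quality with 6 arrays, as the interval is over genes rather than arrays. S replicate 1 had the highest actin ratio and the lowest signal for 14 of the 15 genes. A larger share of medulla stays open: the collecting duct and inner medulla list had a median of 0.14 (-0.0084 to 0.19), below the 0.26 of the heat shock list, but its members went both ways, with an SD of 0.16. Handling or stress before the RNA was frozen stays open too, since the immediate early genes were higher, at 0.21 (0.12 to 0.33, adjusted p = 0.000436), as that cause would need. Their adjusted p was 0.497 with an estimated correlation and 0.129 without S replicate 1, so a difference in handling may rest on that array. A strain difference in chaperone expression, as the design would allow, remains an untested hypothesis beside them.

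The adrenal genes on congenic replicate 3 are consistent with adrenal gland RNA in that pool. Of 20 genes in a second adrenal set, 10 were tested, some of which kidney also expresses. The tested genes lay above the other 5 arrays there by a median of 0.53 (0.12 to 2.28). Akr1b7 was at 2214, and Fdx1 at 1588 against 653 to 706. The mean used by the filter included that array, so genes high there were more likely to be tested. The median covers the tested genes only. A change of the congenic strain was argued against, as the other 2 congenic arrays differed from the S mean by a median of 0.050 (-0.12 to 0.094) over the adrenal list. Akr1b7 is an exception, at 58.3 and 101 on those arrays against 18.2 to 32.2 on the S arrays, so a strain difference in that gene stays open.

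The liver genes on congenic replicate 1 are consistent with liver RNA in that pool or on that array. Of 24 genes in a second liver set, 8 were tested, several of which, such as Rgn and Hpd, kidney also expresses. The tested genes lay above the other 5 arrays there by a median of 0.87 (0.25 to 1.42), with Fga at 599 against 206 to 264. Here too the filter's mean included the high array, and the median covers the tested genes only. A strain change was argued against, since the other 2 congenic arrays differed from the S mean by a median of -0.093 (-0.34 to 0.0035). Carry-over at dissection, RNA extraction or hybridisation was not tested apart.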
